A study of Strongylocentrotus purpuratus with 15 samples.

How the data were processed

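Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, or by Omni-ATAC, a later version of the protocol with other detergents. The series holds 15 samples of the purple sea urchin Strongylocentrotus purpuratus in 8 groups. Embryos at the 4-cell stage and at 8, 12 and 20 h were assayed by ATAC-seq, and embryos at 72 h by both protocols. Red spherule cells (RSC), the pigmented coelomocytes purified from the coelomic fluid of adult animals, were also assayed by both. Per the labels, embryos were kept at 15 °C, nuclei were prepared on density gradients, and the lysis and gradient solutions for RSC held added detergent or albumin. Per the labels, the 12 h samples are a new mapping of libraries from an earlier series. The labels call the replicates bioreplicates and do not say whether replicates came from different parents or batches of embryos. The p values of the grouping and gene-boundary tests therefore measure the spread between these samples. Those of the gene list tests compare genes within these libraries, and genes are not replicates.

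The authors mapped the reads to the Sp5.0 genome (series design text) and called peaks with MACS2 (no version given). The aligner, the read filters and the peak settings are not given in the sources used here. For 12 libraries, 2 of each of 6 groups, the deposited peak list gives each peak's interval and summit, the -log10 p and the -log10 q of the peak in its own list, and its fold enrichment over the local background. The deposited pooled list of RSC Omni-ATAC holds the same columns, a -log10 p, a -log10 q and a fold enrichment. The other 6 pooled lists (5 ATAC groups of embryos and RSC ATAC) are deposited as other values, intervals only, with a start and an end and no value per peak. The 72 h ATAC and RSC Omni-ATAC samples were used only through their pooled lists, which have no replicates. The names of some lists differ from the labels, which were followed. Those of 4-cell replicate 1 and of the pooled 4-cell list carry 8C, that of the pooled 72 h ATAC list joins 3 library names for 2 samples, and that of the RSC Omni-ATAC list names T1 and T2 for 1 sample. What these pooled lists hold is therefore uncertain. Coverage tracks were not used here. The lowest -log10 p lay just above 2, a p of 0.01, in 11 of the 12 lists. The list of 4-cell replicate 2 held exactly 300000 peaks, with a lowest -log10 p of 3.61.

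A peak's -log10 p grows with depth, so it was used only to rank the peaks of one library. Each library's summits were reduced to windows that do not overlap, best p first, and the 50000 with the highest -log10 p were kept. The lowest -log10 q among kept peaks was 5.19. An atlas of 166838 regions was built from the kept peaks of the 12 libraries by taking the best-ranked summits with 200 bp on each side. A region was called present in a library with a kept summit in it, and absent from a library with no summit in it anywhere in its full list. A region with a peak below the kept ones was neither. The rank percentile of a region in a library is 100 for the strongest kept peak and near 0 for the weakest. The read depth of the libraries is unknown, since the lists give no read counts. The number of listed peaks stands in for it, and no counting interval of a library's depth can be given. Wilson 95% intervals are given for shares of regions and cover counting error only.

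The gene table of the RefSeq annotation of Spur_5.0 gives each gene's symbol, number, start and end without a scaffold name, strand or product name. Runs of consecutive table genes were placed on scaffolds through the peaks at gene boundaries, and this was checked along each scaffold. In each of 145 tiles of 6 Mb, gene boundaries met peaks at least 2.55 times as often as after a shift of the genes (median 4.66 times). The best scaffold for a run exceeded the next by 1.72 to 6.56 times. This placed 30064 of 33490 genes on 21 scaffolds, 24774 of 27433 protein-coding genes among them. Of these, 249 have a symbol other than LOC and a number. Without strand, the start of a gene cannot be told from its end, so the planned share of peaks at transcript starts was measured as the share within 1 kb of either gene boundary. These shares take only peaks and regions on the placed scaffolds. At 199990 random positions on the placed scaffolds the share was 11.2%.

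Replicate grouping was tested by the mean Jaccard index of region presence within the 6 pairs, against all 10395 divisions of the 12 libraries into pairs (exact permutation test, one-sided). The gene-boundary share was tested over the same divisions by the sum of squares between pairs. Gained regions at a step were present in both replicates of the later group and absent from both of the earlier one, and lost regions the reverse. With 2 libraries against 2, the smallest p of an exact two-sided test is 0.333, so these counts have no p. They stand beside the same counts for the 2 crossed divisions of the same 4 libraries, each with 1 library of either group on each side. RSC-only regions were present in both RSC ATAC libraries and absent from all 10 embryo libraries. Embryo-constant regions were present in all 10, and those absent from both RSC ATAC libraries were counted.

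Of 22 gene lists, 18 have a placed gene and 7 have at least 5: coelomocyte and immune genes, dorsoventral ectoderm, early zygotic genes, endoderm, FGF, VEGF and ETS genes, skeletogenic genes, and TGF-beta and BMP genes. For each list and each of 12 sets of regions, the number of genes with a region in the gene or within 10 kb was set against 10000 random lists matched on locus length, a two-sided permutation test over genes, with Benjamini-Hochberg adjustment over the 84 tests and a threshold of 0.05. Genes were named by a rule: list members, at most 10, and the 5 best-ranked genes with a symbol whose gained or lost region lies within 1 kb of a gene boundary, the 3 best-ranked regions of each set, and a fixed set of marker genes where the table names them. A symbol took the place of a product name in that rule. Genes named for a region elsewhere in the gene or within 10 kb of it fall outside the rule and were chosen after their values were seen. The groups, contrasts, tests, lists, naming rule and alternative settings were fixed before the data were examined. Outside this plan were the tests of the gene-boundary share of RSC against the embryo libraries and among the embryo groups alone. The alternatives and tests named below as chosen later were outside it too.

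Results were recomputed, each under those of these settings that apply to it, with 25000 or 100000 kept peaks, with all peaks at a -log10 q of at least 2, with ranking by fold enrichment, with 100 or 500 bp on each side of the summit, with absence judged on equally long lists, with presence by overlap, and without each library that enters it in turn. The grouping and the gene-boundary share had no settings of absence or overlap, and the protocol overlaps none of kept peaks, ranking or width. The planned motif tests and the 1 kb upstream promoters were not run, since neither a genome sequence nor strand was used here. On data simulated from the list of 20 h replicate 1, with 200 regions planted in each direction, 69% of gained and 70.5% of lost regions were called. The planted regions were kept peaks with no other summit close by, deleted wholly from both libraries of a side. These shares may therefore be too high for crowded peaks or for peaks that only weaken. The other calls, 444 and 374, were about as many as the crossed divisions gave, 405 and 425. The grouping and gene-boundary tests were simulated on random numbers without peaks, and the list test on random draws of atlas regions. With no effect, 5.5% of 200 simulations gave a p of at most 0.05 in the grouping test, 7% in the gene-boundary test and 0.5% in the list test. With large planted effects 100%, 99% and 100% did, which does not measure the power for effects of the size seen here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used.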

Results

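Open chromatin of purple sea urchin embryos and of adult red spherule cells (RSC) was compared through the peaks of ATAC-seq and Omni-ATAC libraries. The 15 samples comprised 2 each of 4-cell, 8 h, 12 h and 20 h embryos by ATAC-seq, 2 of 72 h embryos by ATAC-seq and 2 by Omni-ATAC, 2 of RSC by ATAC-seq and 1 of RSC by Omni-ATAC. For 12 libraries, 2 in each of 6 groups, the deposited list of the library itself was used. The 72 h ATAC samples entered only through 1 pooled list, and so did the RSC Omni-ATAC sample, so neither has an error, and the names of these lists leave open which libraries they pool. The list names also carry 8C for 4-cell replicate 1 against the 4-cell stage of its label, so the stage of that library is in doubt. The 4-cell lists held 193189 and 300000 peaks, the 8 h lists 166426 and 219108, and the 12 h lists 281439 and 263452. The 20 h lists held 210152 and 207656, the 72 h Omni-ATAC lists 221367 and 245445, and the RSC ATAC lists 255375 and 272209. As means ± SD (n = 2), the list length ran from 192767 ± 37252 peaks at 8 h to 272446 ± 12719 at 12 h, with 246594 ± 75527 at the 4-cell stage. The 7 pooled lists held 188318 to 245573 intervals, and the RSC Omni-ATAC list had 262342 summits in 225025 intervals. Read depth is unknown. The lowest -log10 p among the 50000 peaks kept per library ran from 7.27 in 4-cell replicate 1 to 22.3 in RSC replicate 2.

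The first question was whether libraries of 1 group share more open regions than libraries of different groups. The atlas held 166838 regions of 400 bp, of which 2655 were present in all 12 libraries and 5844 in all 10 embryo libraries. The mean Jaccard index (shared regions over all regions of a pair) was 0.529 for the 20 h pair, 0.492 for 72 h, 0.430 for 8 h, 0.395 for 12 h, 0.378 for RSC and 0.308 for the 4-cell pair. Between groups, 8 h and 12 h (mean 0.376), 12 h and 20 h (0.374), 8 h and 20 h (0.373) and 20 h and 72 h (0.369) were closest. RSC lay farthest from 20 h (0.166) and 72 h (0.172). The mean over the 6 pairs was 0.422, against 0.284 for libraries of different groups. No other of the 10395 divisions into pairs reached it (highest other 0.413), which gives an exact permutation p of 9.62e-05, one-sided, the smallest these divisions allow. The 4-cell pair is the exception within this result. 4-cell replicate 2 had an index of 0.308 with its own replicate, 0.326 with 12 h replicate 1, and 0.305 and 0.322 with the RSC libraries. 4-cell replicate 1 in turn was closer to the 8 h libraries (0.343 and 0.324) and the 12 h libraries (0.328 and 0.323) than to 4-cell replicate 2. By the names of the lists, 4-cell replicate 1 and the 8 h and 12 h libraries came from 1 sequencing run, and 4-cell replicate 2 from another. Run and group cannot be told apart for the other groups.

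**Figure D1:**
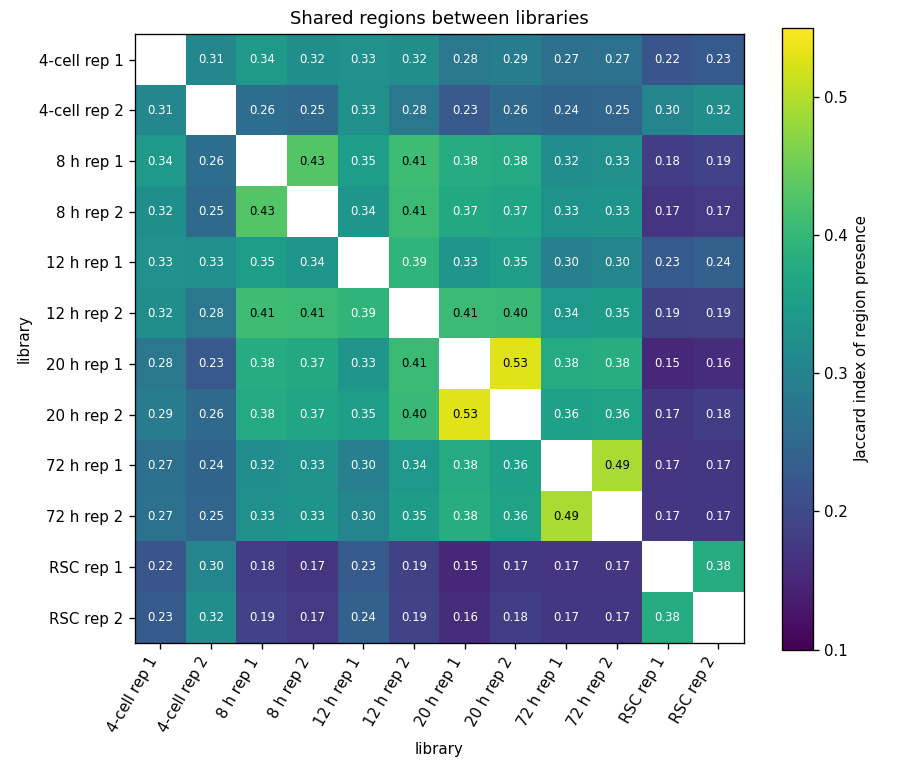
Jaccard index of region presence for each pair of the 12 libraries, both axes listing the libraries by group and replicate. The 20 h pair has the highest index of the 6 replicate pairs (0.529) and the 4-cell pair the lowest (0.308).

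Peaks at gene boundaries, where promoters and gene ends lie, took different shares in the groups. At the 4-cell stage 19.8% ± 2.25 (SD, n = 2) of kept peaks lay within 1 kb of a gene boundary, at 8 h 25.2% ± 0.872, at 12 h 25.8% ± 2.92, at 20 h 26.8% ± 0.636 and at 72 h 27.4% ± 0.0414. In RSC by ATAC-seq the share was 14.2% ± 0.225, and 11.2% of random positions lay as near. Away from boundaries, 54.8% ± 1.31 of RSC peaks lay within genes, against 38.5% at 72 h and 50.9% ± 5.08 at the 4-cell stage, where replicate 2 (54.5%) exceeded RSC replicate 1 (53.9%). In the RSC libraries 5969 and 5999 of 24774 protein-coding genes had a boundary peak (24.1% and 24.2%), against 11191 and 11184 (45.2% and 45.1%) in the 72 h libraries. Of 13 dorsoventral ectoderm genes, 69.2% and 76.9% had a boundary peak in the 72 h libraries and 38.5% and 46.2% in the RSC libraries. Of 11 coelomocyte and immune genes, 27.3% and 18.2% did at 72 h and 45.5% and 54.5% in RSC, but also 45.5% in 4-cell replicate 2 and in 12 h replicate 2 and 54.5% in 20 h replicate 2. Of 12 skeletogenic genes, 58.3% did in both 72 h libraries and 75% in both RSC libraries, and of the 7 genes of the FGF, VEGF and ETS list 71.4% did in all 4. The shares were lower in RSC for the endoderm (87.5% in both 72 h libraries, 62.5% and 75% in RSC), early zygotic (62.5% in both, 25% and 37.5%) and TGF-beta and BMP lists (80% and 60%, 40% in both). No test was run on the shares of these lists.

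The share differed between groups beyond the spread between replicates, with 58 of the 10395 divisions as extreme (exact permutation p = 0.00558, one-sided). The RSC ATAC libraries lay below all 10 embryo libraries (embryo mean 24.99% ± 3.12), with an exact two-sided permutation p of 0.0152, the smallest of 66 divisions. These divisions exchange single libraries, although replicates were alike, so the p is too small for RSC against embryos as groups. This comparison and the next were not among the planned tests. Among the 5 embryo groups alone the difference did not pass the threshold (945 divisions, exact permutation p = 0.0614). The pooled RSC Omni-ATAC list had 18.4% of its kept peaks at gene boundaries. This lay above the RSC ATAC libraries and also above 4-cell replicate 2 (18.2%), and below the other 9 embryo libraries. Among the 5000 strongest peaks its share was 31.4%, against 15.5% and 15.3% in the RSC ATAC libraries and 31.0% in 4-cell replicate 2, the lowest of the embryo libraries. The other embryo libraries ran from 47.6% to 66.2%, with 66.2% and 64.7% in the 72 h Omni-ATAC libraries.

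**Figure D2:**
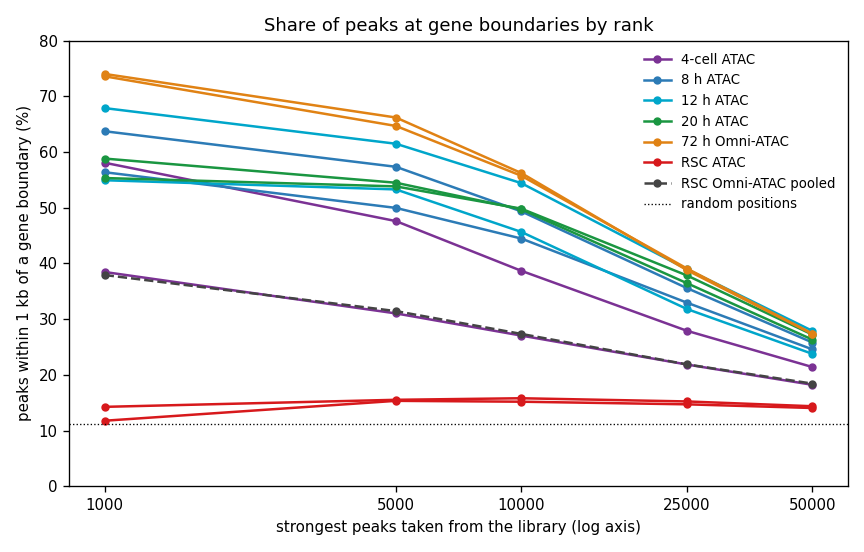
Percentage of peaks within 1 kb of a gene boundary among the strongest 1000 to 50000 peaks (log axis), with a line for each library. The pooled RSC Omni-ATAC list is dashed and random positions are dotted. Among all 50000 kept peaks the RSC ATAC libraries (14.37% and 14.05%) lie below every embryo library, the lowest of which is 4-cell replicate 2 at 18.2%.

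The next comparisons follow development from step to step. Between the 4-cell stage and 8 h, regions were gained at the boundaries of 8 genes with a symbol and lost at 2. The strongest gained region at a gene boundary with a symbol was at eif4a (gene 575736), an RNA helicase of translation initiation, on scaffold NW_022145597.1 of Spur_5.0 at 31651667 to 31652066, 244 bp from the boundary. Its mean rank percentile at 8 h was 65.8 (n = 2, lower replicate 55.6). Gained regions also lay at the boundaries of eif4e3 (gene 754252, percentile 48.1), of SPARC (gene 591523, 40.2), a matrix protein, and of SpAN (gene 593517, 29.8), a protease of the blastula. The SpAN region (NW_022145615.1, 1369462 to 1369861) lay 642 bp from the gene and was listed in the 8 h and 12 h libraries and in no other. VEB4 (gene 373489), a gene of the very early blastula, ECaSt/PDI (gene 373305), ags (gene 593595) and Hlf (gene 593063) made up the rest, at percentiles of 22.1 to 44.2. Lost regions at a boundary lay at MMP16 (gene 577070, 4-cell percentile 54.6), a metalloproteinase, and mgb (gene 585663, 10.7). Without regard to symbols, the strongest gained region lay 562 bp from LOC115924320 (NW_022145600.1, 7240533 to 7240932, percentile 93.5), and the strongest lost region within LOC105444500 (NW_022145605.1, 29164409 to 29164808, 97.3).

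In all, 1265 regions were gained at 8 h and 569 lost, against 192 to 287 in the crossed divisions, while 11069 were present in all 4 libraries. Of the gained regions 32.6% (95% Wilson interval 29.96 to 35.4) lay at a gene boundary, against 11.8% (9.33 to 14.7) of the lost ones. Of the early zygotic list, 2 of 8 genes had a gained region at their locus (Lim1 and SpAN, permutation p = 0.0894), and of the skeletogenic list 2 of 12 (erg and ets1, p = 0.281). The same ETS genes were the 2 of 7 of the FGF, VEGF and ETS list (permutation p = 0.160). None of these passed after adjustment. The counts rest on the replicate rule, since dropping a library relaxes it by construction. Gained regions numbered 3671 without 4-cell replicate 1, 3118 without 4-cell replicate 2, 4504 without 8 h replicate 1 and 4160 without 8 h replicate 2, and lost regions 4145, 4804, 1562 and 2042. Lost regions outnumbered gained ones without either 4-cell library, with 100000 peaks (3639 against 3450) and with all peaks at a -log10 q of at least 2 (15066 against 5297), so which direction was larger rests on the setting. The value without 4-cell replicate 2 is also the one within a single sequencing run, as far as the list names tell.

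From 8 h to 12 h the one region gained at the boundary of a gene with a symbol lay at DVR1 (gene 373534), a TGF-beta family ligand, 89 bp from the gene (NW_022145613.1, 6593680 to 6594079), at a percentile of 20.3 (n = 2, lower replicate 1.54). With BMP1, DVR1 made 2 of 5 genes of the TGF-beta and BMP list with a gained region (permutation p = 0.0522, adjusted 0.513). The strongest gained region lay within 1 kb of LOC577847 (NW_022145607.1, 40969374 to 40969773). It had been lost at 8 h (4-cell percentile 92.1) and was gained at 12 h (95.1). No gene with a symbol had a lost region at its boundary, and the strongest lost region lay within LOC105438386 (NW_022145603.1, 27769192 to 27769591, percentile 92.4).

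By the list names alone this step lies within 1 sequencing run, while the labels take the 12 h libraries from an earlier series. A batch difference is therefore not excluded. The step had 657 gained regions, above the 140 to 362 of the crossed divisions, and 340 lost regions, which did not exceed them. In all 4 libraries 16675 regions were present. Of the gained regions 19% (95% Wilson interval 16.1 to 22.3) lay at a gene boundary, and of the lost ones 15.7% (12.1 to 20.2). Gained regions numbered 1745 without 8 h replicate 1, 1988 without 8 h replicate 2, 3798 without 12 h replicate 1 and 4875 without 12 h replicate 2, and lost regions 2262, 2279, 875 and 1620, the rule again being relaxed by construction. Lost regions outnumbered gained ones without either 8 h library and with absence judged on lists of equal length (763 against 758). With 100000 peaks 4019 regions were gained, more than at 8 h (3450) or 20 h (3805), and with all peaks at a -log10 q of at least 2 24515 were.

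At 20 h, regions at the boundaries of VEB4 and SpAN were lost, and no list test of gained or lost regions passed the adjusted threshold. No gene with a symbol had a gained region at its boundary, so the genes named here for a gain fall outside the naming rule and were chosen after their values were seen. Of the skeletogenic list 3 of 12 genes had a gained region: ets1 (20 h percentile 42.2), SM50 (34.6), a spicule matrix protein, and P16 (50.2). The random lists gave 0.621 on average (permutation p = 0.0412, adjusted 0.499). Of the dorsoventral ectoderm list 3 of 13 did, Tbx2/3, FoxG (57.1) and Dlx (50.5), with permutation p = 0.0550. Of the endoderm list 2 of 8 did, FoxA (56.0), a transcription factor of the gut, and wnt1 (permutation p = 0.141), while 1 of 8, GATAe, had a lost region (12 h percentile 8.90, NW_022145613.1, 366306 to 366705, permutation p = 0.390), which was gained again at 72 h. Regions lost at a gene boundary lay at VEB4 (NW_022145607.1, 33707128 to 33707527, 76 bp from the gene), with a 12 h percentile of 76.3 (n = 2, lower replicate 73.6), and at SpAN, where the region gained at 8 h had reached 74.4 at 12 h (lower replicate 67.4). The strongest gained region lay within LOC585718 (NW_022145612.1, 30856667 to 30857066) and had been lost at 12 h (8 h percentile 86.2, 20 h percentile 96.8). The strongest lost region lay between genes, 18800 bp from LOC764348 (NW_022145596.1, 33316320 to 33316719, 97.1).

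In all, 1228 regions were gained at 20 h and 485 lost, against 79 to 278 in the crossed divisions, with 17277 present in all 4 libraries. Gene boundaries held 17.01% (95% Wilson interval 14.9 to 19.3) of the gained and 17.7% (14.5 to 21.5) of the lost regions. Gained regions numbered 2217 without 12 h replicate 1, 3562 without 12 h replicate 2, 3045 without 20 h replicate 1 and 3715 without 20 h replicate 2, and lost regions 2992, 3348, 1277 and 1090. Dropping a library relaxes the rule by construction. Lost regions outnumbered gained ones without 12 h replicate 1 and with all peaks at a -log10 q of at least 2 (20005 against 9442). With all peaks at a -log10 q of at least 2, 10 of the 12 skeletogenic genes had a gained region (adjusted permutation p = 0.0336), and with absence judged on equally long lists 7 of the 13 dorsoventral genes did (adjusted permutation p = 0.0168).

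**Figure D3:**
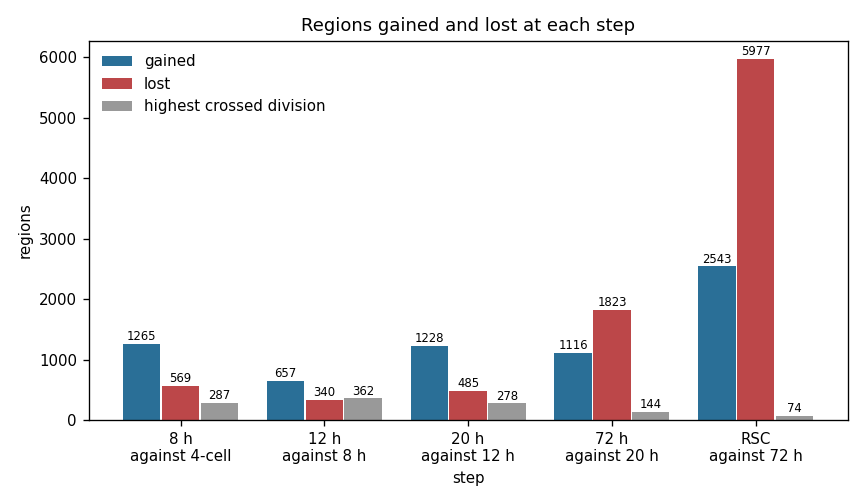
Number of regions gained and lost at each step, with the highest count of the crossed divisions of the same libraries. Of the 5 steps, RSC against 72 h has the most regions in both directions (2543 gained and 5977 lost), and lost regions at 12 h (340) do not exceed the highest crossed count (362).

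Between 20 h and 72 h the protocol changed along with the age, from ATAC-seq to Omni-ATAC. At 72 h a region was gained at the boundary of HMG1 (gene 373332), an HMG-box chromatin protein (NW_022145596.1, 1588338 to 1588737, 493 bp from the boundary), at a percentile of 84.0 (n = 2, lower replicate 82.3). Others lay at eef1G (gene 574070, 20.9), a translation elongation factor, and cdk4 (gene 373289, 19.7), a cell cycle kinase, and all of these had a peak in the pooled 72 h ATAC list too. A region was lost at PMAR1 (gene 373266), a repressor active in the micromere lineage (NW_022145605.1, 1332715 to 1333114, 128 bp from the gene, 20 h percentile 28.4). It had no 72 h ATAC peak. Another was lost at SpP19L (gene 373524, 38.4) and had one. The strongest gained region lay within LOC582566 (NW_022145612.1, 50545957 to 50546356, 95.1). The strongest lost region, 9702 bp from LOC115920948 (NW_022145594.1, 17159150 to 17159549, 92.8), had a peak in the 72 h ATAC list, and so did the next ones, near LOC594743 and LOC579271.

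Of the dorsoventral ectoderm list 4 of 13 genes had a region gained at 72 h: Tbx2/3 (percentile 72.1), Gsc (64.9), NK2.2 (34.0) and BMP2/4 (13.2), the last a ligand of the BMP family. The random lists gave 0.577 on average (permutation p = 0.0046, adjusted 0.193). With presence by an overlap of at least 0.5 of the region the count was 8 of 13 (adjusted permutation p = 0.0168). Lost regions lay at 2 of the 13, Tbx2/3 (20 h percentiles 54.2 and 29.4) and Dlx (50.5), with 1.03 in random lists and permutation p = 0.552, and the Dlx region and 1 of those of Tbx2/3 had been gained at 20 h. Of the endoderm list 2 of 8 had a gained region, FoxA (61.9) and GATAe (49.8 and 40.4), with permutation p = 0.124, and FoxA also had a lost one (89.7). Of the skeletogenic list none of 12 had a gained region and 2 a lost one, SpP19L and SM50 (permutation p = 0.484). Of the early zygotic list 3 of 8 genes had a lost region, Hes, Lim1 and PMAR1 (permutation p = 0.0166, adjusted 0.349), and 2 of 8 a gained one, Hes and otx (p = 0.0372). The genes named here for regions away from a boundary were chosen after their values were seen.

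At this step 1116 regions were gained and 1823 lost, against 66 to 144 in the crossed divisions, with 18254 present in all 4 libraries. Of the gained regions 19.9% (95% Wilson interval 17.6 to 22.4) lay at a gene boundary, and of the lost ones 13.03% (11.5 to 14.7). Of the gained regions 913 (81.8%) had a peak in the pooled 72 h ATAC list, while 1056 (57.9%) of the lost ones had none there. The list of 72 h ATAC peaks covered 96.2% of all regions present in both 72 h Omni-ATAC libraries, and 28.3% after a shift of 50 kb, but also 91.3% to 99.2% of the regions present in both libraries of the other groups. Gained regions numbered 2596 without 20 h replicate 1, 2001 without 20 h replicate 2, 3410 without 72 h replicate 1 and 3604 without 72 h replicate 2, and lost regions 4636, 4635, 3181 and 3712, with the rule relaxed by construction. Gained regions outnumbered lost ones without 72 h replicate 1 and with all peaks at a -log10 q of at least 2 (15615 against 15076).

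**Figure D4:**
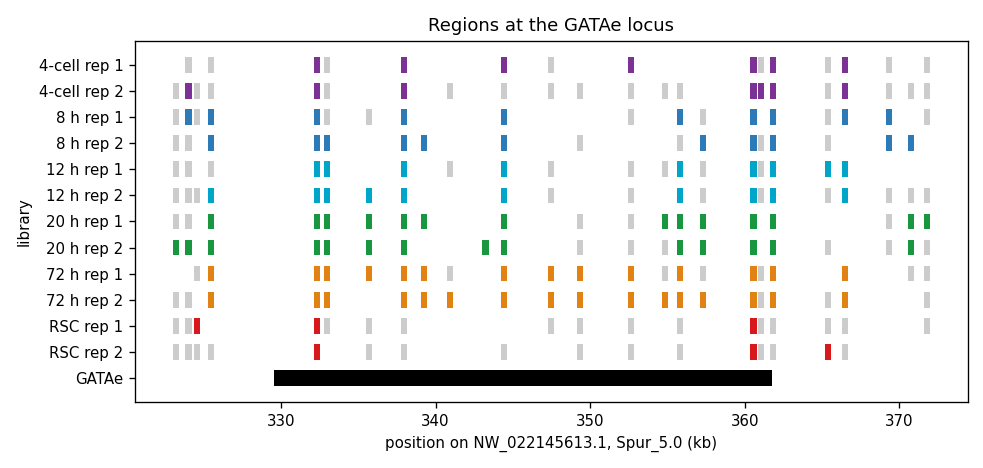
Regions at the GATAe locus on NW_022145613.1 (position in kb), by library, with the gene drawn from 329575 to 361799 bp. In both replicates, 13 of the 26 regions are present at 72 h and 2 in RSC.

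Marker genes of cell lineages had different numbers of regions at their loci over time. At GATAe (gene 408052), a transcription factor of the endoderm, 5, 7, 8, 11 and 13 of 26 regions were present in both replicates at the 4-cell stage, 8 h, 12 h, 20 h and 72 h, and 2 in RSC. At FoxA the counts were 3, 6, 5, 6 and 8 of 12, and 3 in RSC. At gcm, a transcription factor of pigment cells, they were 2, 4, 3, 2 and 0 of 13, and 1 in RSC. Alx1, a regulator of skeletogenic cells, had 11, 18, 10, 12 and 11 of 34, and 9 in RSC, and SM50 had 3, 2, 2, 5 and 4 of 12, and 6 in RSC. The germline genes vasa and Nanos2 had 5, 4, 4, 5 and 5 of 19 and 3, 6, 2, 7 and 2 of 12, and 7 and 2 in RSC. Hes had 2, 5, 4, 5 and 5 of 10, and 2 in RSC, and blimp1/krox had 6, 5, 4, 6 and 4 of 17, and 2 in RSC. PMAR1 had 1 of 3 from 8 h to 20 h, Endo16 1 of 4 at 20 h, and msp130 none of 3. No test was run on these counts.

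RSC, differentiated adult cells, were set against 72 h embryos. This contrast combines cell type, age and protocol, since the 72 h pair was made by Omni-ATAC and the RSC pair by ATAC-seq. RSC lacked a gene-boundary region of 25 genes with a symbol that was present at 72 h. The strongest was at rib74 (gene 378944, NW_022145613.1, 14082714 to 14083113, 88 bp from the boundary), with a mean rank percentile of 98.7 at 72 h (n = 2, lower replicate 98.6). BMP2/4 (gene 373196, NW_022145611.1, 36745506 to 36745905, 141 bp) had 90.4 and Sp-Smad2/3 (gene 577345, NW_022145612.1, 428080 to 428479, 24 bp), which carries TGF-beta and activin signals, had 90.4. mvp (gene 575735, NW_022145605.1, 15840245 to 15840644, 147 bp), the major vault protein, had 87.2 and hsp110 (gene 373300), a chaperone, 89.2. The other list members were NFkB (gene 373533, 82.6), the ribosomal protein genes rps14 (gene 574895, 79.1) and rpl36 (gene 574853, 67.3), delta (gene 373299, 77.7), a Notch ligand, Nanos2 (gene 751842, 49.1) and NK2.1 (gene 373506, 38.9), and also the cell cycle genes Chk1 (gene 592974, 53.4) and cdk4 (19.7). One gene with a symbol, AMAS4, had a gained region at its boundary. Of the 25 regions, 15 had a peak in the RSC Omni-ATAC list, among them those of rib74, BMP2/4, Sp-Smad2/3, mvp, NFkB, rps14, rpl36 and Chk1. Those of hsp110, delta, Nanos2, NK2.1 and cdk4 had none. The strongest lost regions lay 76 bp from LOC579722 (NW_022145611.1, 13107437 to 13107836, 99.8), 20 bp from LOC583510 and 105 bp from LOC581769, and each had a peak in the RSC Omni-ATAC list.

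Some of the regions gained in RSC lay at immune genes. Of the coelomocyte and immune list 6 of 11 genes had one at their locus: Tlr1.1 (percentile 75.8), a Toll-like receptor, the complement genes c3 (85.7, 66.5 and 27.4) and bf (60.5), the scavenger receptor gene SRCR12, and AMAS2 and AMAS4, amassins of coelomocyte clotting that share 1 region. That region lay 922 bp from AMAS4 (gene 579980, NW_022145609.1, 35087632 to 35088031, 37.6, lower replicate 34.0), had an RSC Omni-ATAC peak, and was the one named by the rule. The others were chosen after their values were seen. The c3 region at 85.7 (NW_022145610.1, 4204558 to 4204957) was kept in both 20 h libraries and in 12 h replicate 1, and was one of those lost at 72 h (20 h percentile 36.2). The regions of AMAS2 and AMAS4, of bf and of c3 also had a peak in the pooled 72 h ATAC list, and those of Tlr1.1 and SRCR12 had none. The random lists gave 1.30 on average (permutation p = 0.0010, adjusted 0.0840), so the excess did not pass the threshold. These lists were drawn gene by gene, while the region shared by AMAS2 and AMAS4 counts for both genes. The p values for this list may therefore be too small. Against random lists drawn from genes with a symbol alone the permutation p was 0.0068 (adjusted 0.571). Without 72 h replicate 1 the count was 8 of 11 (adjusted permutation p = 0.0336), and with Fisher's exact test, without matching on length, the adjusted p for the 6 of 11 was 0.0156. The strongest gained regions lay within LOC105444375 (NW_022145598.1, 15550495 to 15550894, 99.9), 29475 bp from LOC583606 (99.7) and within LOC575000 (99.7).

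Genes of every list had regions lost in RSC, and no list passed the adjusted threshold. These were 5 of 8 early zygotic genes (SoxB1, Hes, Lim1, otx and SpAN, 1.56 in random lists, permutation p = 0.0140, adjusted 0.349) and 7 of 13 dorsoventral ectoderm genes (Tbx2/3, NK2.2, Gsc, FoxG, BMP2/4, Dlx and IrxA, 3.29 in random lists, p = 0.0416, adjusted 0.499). Of the endoderm list 4 of 8 did (lox, eve, GATAe and wnt1, permutation p = 0.262), and of the FGF, VEGF and ETS list 3 of 7 (p = 0.759). Of the skeletogenic list 2 of 12 did (2.98 in random lists, permutation p = 0.789), of the coelomocyte and immune list 2 of 11 (3.21 in random lists, p = 0.654) and of the TGF-beta and BMP list 2 of 5 (1.69 in random lists). No lost region of Lim1, Tbx2/3, NK2.2, Gsc, FoxG, IrxA, eve or GATAe had a peak in the RSC Omni-ATAC list. Those of SoxB1, SpAN and Dlx had one, and so did some of those of Hes, otx, BMP2/4, lox and wnt1. Over the 7 lists and all 12 sets of regions, 0 of 84 tests passed an adjusted p of 0.05, and 7 had an unadjusted p of at most 0.05, each an excess. With lists this short a deficit could hardly reach that p. For regions gained in RSC, 0 of 13 dorsoventral genes against 1.25 in random lists gave a permutation p of 0.531.

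In all, 2543 regions were gained in RSC and 5977 lost, against 64 to 74 in the crossed divisions. These were 9.60% of the regions present in both RSC libraries and 19% of those present in both 72 h libraries, with 7265 present in all 4. Of the lost regions 45.7% (95% Wilson interval 44.4 to 47.0) lay at a gene boundary, and of the gained ones 9.10% (8.01 to 10.3). The pooled 72 h ATAC list had a peak in 1799 (70.7%) of the regions gained against the 72 h Omni-ATAC pair, which leaves 744 listed at 72 h by neither protocol, and in 5060 (84.7%) of the lost ones. In the RSC Omni-ATAC list 2462 (96.8%) of the gained regions had a peak, and so did 2469 (41.3%) of the lost ones, which leaves 3508 lost regions without a peak in either protocol. Against the 20 h pair, made by ATAC-seq as the RSC pair was, 2471 regions were gained and 7807 lost, a comparison added after the data were seen. Gained regions numbered 4195 without 72 h replicate 1, 4902 without 72 h replicate 2, 9172 without RSC replicate 1 and 9570 without RSC replicate 2. Lost regions numbered 9907, 9812, 8393 and 9346 without the same libraries. Dropping a library relaxes the rule by construction. Gained regions outnumbered lost ones without either RSC library, where presence was asked of a single RSC library but of both 72 h libraries. They also did with all peaks at a -log10 q of at least 2 (29016 against 20545), where the lists differ in length. The excess of lost regions held under the other settings, each with equally many kept peaks per library, but not under all.

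Against the 10 embryo libraries at once, 249 regions were present in both RSC ATAC libraries and listed in none of the 10, and 130 of the 5844 embryo-constant regions (2.22%) were absent from RSC. For the 60 pairs of libraries from different groups, the count present in the pair and absent from the others was at most 33 (median 6.5), and the count absent from the pair alone at most 11 (median 0). A set of its own was not particular to RSC. Under the same rule the 20 h pair had 184 such regions, the 72 h pair 147, 12 h 30, 8 h 28 and the 4-cell pair 3. At most 1 region was absent from any of these pairs alone. The RSC-only regions included 1 within SRCR12 (gene 373431, NW_022145609.1, 39080340 to 39080739, percentile 54.5), the one gene with a symbol among them, chosen after its value was seen. The strongest lay 92489 bp from LOC579644 (NW_022145600.1, 20906205 to 20906604, 96.7), 11999 bp from LOC592739 (94.0) and within LOC115925094 (93.2). Embryo-constant regions absent from RSC lay at the boundaries of mvp (mean percentile 89.6, n = 10), rib74 (86.3) and Nanos2 (75.9, NW_022145605.1, 14906729 to 14907128). The strongest lay 4 bp inside LOC584519 (NW_022145612.1, 20100656 to 20101055, 96.96), 7375 bp from LOC576281 (96.95) and 7 bp inside LOC580278 (95.4). Gene boundaries held 10.7% (95% Wilson interval 7.31 to 15.4) of RSC-only regions and 71.5% (63.0 to 78.8) of the absent embryo-constant ones, against 44.0% of all embryo-constant regions.

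The pooled 72 h ATAC list, which the rule does not use, had a peak in 58 (23.3%) of the RSC-only regions and in all 130 of the absent embryo-constant ones. After a shift of 50 kb that list met 26.9% of the regions present in both RSC libraries, so the 23.3% does not exceed such overlap. The RSC Omni-ATAC list had a peak in 231 (92.8%) of the RSC-only regions and in 92 (70.8%) of the 130 absent ones, including those of mvp, rib74, LOC584519 and LOC580278 but not those of Nanos2 and LOC576281. The RSC-only count was 384 without 4-cell replicate 2, 2153 without RSC replicate 1 and 2523 without RSC replicate 2. The count of absent embryo-constant regions was 714 without 4-cell replicate 2, 311 without RSC replicate 1 and 438 without RSC replicate 2. Each drop relaxes the rule by construction.

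The last comparison set the protocols against each other in RSC. Of the 245032 peaks of the pooled RSC ATAC list, 66.5% met an RSC Omni-ATAC peak, against 18.9% after a shift of 50 kb and 59.0% to 62.8% for the pooled lists of the embryo groups. Of the Omni-ATAC peaks, 75.4% met a peak of the pooled RSC ATAC list, and 54.3% to 68.5% met one of an embryo group's pooled list. The Jaccard index of the Omni-ATAC list was 0.460 with RSC ATAC replicate 1 and 0.342 with replicate 2, 0.327 with 4-cell replicate 2, and 0.214 to 0.273 with the other embryo libraries. With 1 pooled list per protocol, no test was run.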

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

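Alternatives chosen after the data were seen were the 20 h pair in place of 72 h, the added gene lists, the random lists of genes with a symbol, and absence from the RSC Omni-ATAC list as a further condition. The grouping of replicates kept its direction and its side of the threshold under every alternative run, without each library in turn (exact permutation p from 9.62e-05, the smallest possible, to 0.000481) and with exchanges confined to a replicate block (p = 0.00139). So did the gene-boundary share (without each library 0.000962 to 0.0189, within 500 bp of a boundary 0.00279, with a -log10 q of at least 2 0.0346, within a replicate block 0.0208). The counts of gained and lost regions, in contrast, depend on the number of peaks kept, and so does their balance. Which of gained and lost regions were more turned under 4 of 13 alternatives at 8 h, 3 of 13 at 12 h, 2 of 13 at 20 h, 2 of 14 at 72 h and 3 of 14 in RSC. Each turn without a library gave more regions to the group that lost it, for which presence was then asked of a single library. Among the main results, 76 values under the alternatives stayed within their limits and 73 moved, and without each library 54 stayed and 48 moved. Among the others, 336 stayed and 138 moved, and without each library 233 stayed and 3 moved. The 233 include the gene-boundary calls of named genes. Dropping a library only relaxes the rule, so these calls remain by construction and do not measure stability. Of 47 gene-boundary calls for named genes, 23 remained with 25000 peaks, 25 with ranking by fold enrichment, 19 with 500 bp on each side, and all 47 with 100000 peaks. Depth could not be matched, since the lists hold no read counts. The motif tests and the 1 kb upstream promoters were not run. Where counts moved without a library, the rule was relaxed by construction, and with more or fewer kept peaks or a stricter or looser presence the criterion itself selects more or fewer regions. Otherwise the cause was not tested.

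Gained and lost regions are given in that order for 8 h, 12 h, 20 h, 72 h and RSC, each against the group before it, then RSC-only and absent embryo-constant regions. With 25000 peaks there were 384 and 83, 104 and 80, 339 and 139, 251 and 595, and 845 and 3250, then 75 and 40. With 100000 peaks there were 3450 and 3639, 4019 and 1596, 3805 and 2707, 4452 and 5916, and 8186 and 10728, then 1225 and 424. With all peaks at a -log10 q of at least 2 there were 5297 and 15066, 24515 and 3283, 9442 and 20005, 15615 and 15076, and 29016 and 20545, then 5740 and 1391. With an overlap of at least 0.5 of the region there were 2061 and 1466, 1567 and 805, 2332 and 1416, 3063 and 3064, and 4866 and 9744, then 791 and 527. With ranking by fold enrichment, lost regions at 8 h came to 1042, gained regions at 12 h to 1132 and RSC-only regions to 524. With 100 bp on each side, lost regions at 12 h came to 538 and absent embryo-constant regions to 244. With absence judged on lists of equal length, gained regions came to 2030 at 8 h, 1921 at 20 h and 3840 in RSC, lost regions to 763 at 12 h and 9866 in RSC, RSC-only regions to 442 and absent embryo-constant regions to 449. With an overlap of 1 bp, absent embryo-constant regions came to 258. With the pooled 72 h ATAC list as a second condition, lost regions at 72 h came to 1056. With the RSC Omni-ATAC list as a further condition, lost regions in RSC came to 3508 and absent embryo-constant regions to 38.

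Without each library in turn, gained regions ran from 3118 to 4504 at 8 h, 1745 to 4875 at 12 h, 2217 to 3715 at 20 h, 2001 to 3604 at 72 h and 4195 to 9570 in RSC. Lost regions ran from 1562 to 4804 at 8 h, 875 to 2279 at 12 h, 1090 to 3348 at 20 h, 3181 to 4636 at 72 h and 8393 to 9907 in RSC. RSC-only regions ran from 261 to 2523 and absent embryo-constant regions from 1.3e+02 to 714.

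The gene list tests past the threshold numbered 0, and 1 under each of 5 alternatives. These were skeletogenic genes gained at 20 h with a -log10 q of at least 2 (adjusted p = 0.0336), dorsoventral genes gained at 20 h with absence on lists of equal length (0.0168) and at 72 h with an overlap of at least 0.5 of the region (0.0168), and immune genes gained in RSC without 72 h replicate 1 (0.0336) and with Fisher's exact test without matching (0.0156). Without each library the number ran from 0 to 1. The cause was not tested. The share of RSC ATAC peaks on an RSC Omni-ATAC peak came to 60.9% with an overlap of at least 0.5 of the peak and 64.9% with a -log10 q of at least 2, the reverse share to 72.8% and 76.4%, and the share of 72 h regions with a 72 h ATAC peak to 90.0% with an overlap of at least 0.5 of the region and to 92.3% to 92.8% without a library of the pair, where more regions count as present.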

Other observations

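The tests chosen after their results were seen are the share of RSC Omni-ATAC peaks at gene boundaries among all kept and among the strongest peaks. The comparison of regions lost at 72 h with crossed pairs by share was chosen after the share at 20 h was seen. The other tests of explanations below were set down before the values they measure were seen. Regions gained at one step were followed to the later groups. Of the 1265 regions gained at 8 h, 347 (27.4%) were present in both 12 h libraries, 639 (50.5%) in both 20 h libraries, 368 (29.1%) in both 72 h libraries and 17 (1.34%) in both RSC libraries. Of the regions gained at a step, 127 (10.04%) were listed in neither library of the next group after 8 h, 99 (15.1%) after 12 h, 407 (33.1%) after 20 h and 430 (38.5%) after 72 h, the next group there being RSC. Steps that share a pair of libraries are not independent, so no expectation by chance is set beside these counts. Of the 569 regions lost after the 4-cell stage, 184 (32.3%) were present in both RSC libraries, and of the 1823 lost at 72 h, 433 (23.8%) were present in both 8 h libraries. Of the 5977 regions lost in RSC, 3326 (55.6%) were present in both 20 h libraries and 190 (3.18%) in both 4-cell libraries.

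Genes outside the lists with a symbol and a boundary region lost in RSC included HMG1 (72 h percentile 84.0), TBP (83.2), the TATA-box binding protein, NSF (79.2), the vesicle fusion ATPase, rab11 (79.0), SSAP (78.0), dlp (75.7), KIF15 (64.6), a kinesin, CyIIIa (62.1), an actin of the aboral ectoderm, and rab3 (56.6). Of lists added later, eif4e1 (75.5), REJ9 (74.8) and REJ8 (54.8) had one. Those of TBP, HMG1, rab11, SSAP, dlp, eif4e1 and REJ9 had a peak in the RSC Omni-ATAC list. Gene lists added after the data were seen, among them translation factors and ribosomal proteins, brought no test past the threshold (0 of 144, with 9 at an unadjusted p of at most 0.05). Of the translation list 2 of 11 genes, rps14 and eif4e3, had an embryo-constant region that the RSC ATAC libraries lacked at their locus (permutation p = 0.0080, adjusted 0.384), and both of these regions had a peak in the RSC Omni-ATAC list. Region presence in replicates of the same number in different groups was no more alike than in replicates of different numbers (Jaccard index 0.284 against 0.285).

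RSC ATAC peaks lay at gene boundaries less often than the peaks of each embryo library. Weak peaks away from genes are excluded as the whole cause, since among the 5000 strongest peaks the share was 15.5% in the higher RSC ATAC library and 31.0% in the lowest embryo library. A loss of boundary regions in the ATAC preparation of RSC nuclei that Omni-ATAC avoids is not the whole cause, since 38.3% of the lost regions that the RSC Omni-ATAC list lacks too lay at a boundary, against 31.3% of all 72 h regions. As a part of the cause the preparation may matter, since lost regions with an RSC Omni-ATAC peak lay at a boundary in 55.9%. Among the 5000 strongest peaks the RSC Omni-ATAC share was 31.4%, above both RSC ATAC libraries. This was just above 4-cell replicate 2 (31.0%) and below every other embryo library (47.6% to 66.2%). A gap between RSC and 72 h embryos remained with Omni-ATAC used for both. It was 18.4% against 27.3% and 27.4% over all kept peaks, and 31.4% against 66.2% and 64.7% among the 5000 strongest. A difference between adult RSC and embryo cells still cannot be told apart from the preparation. The RSC Omni-ATAC list has no replicates, and its share over all kept peaks lay above 4-cell replicate 2 (18.2%).

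4-cell replicate 2 shared about as many regions with RSC as with 4-cell replicate 1. RSC chromatin mixed into that library cannot be told apart from other causes. Of the 384 RSC regions that no other embryo library lists it listed 135 (35.2%), more than the 18.9% of 12 h replicate 1, the next highest. Its list was also the longest, with 300000 peaks. By kept peaks, equal in number, its share was 2.60%, and 4-cell replicate 1 had 4.59% of its own 283 such regions. Neither the kept peaks of 4-cell replicate 2 (2.08% of the stronger 192 regions, 3.13% of the weaker) nor its listed peaks (32.8% and 37.5%) went with strength in RSC beyond their Wilson intervals. Weak peaks of its long list cannot be told apart either, because among the 10000 strongest peaks its Jaccard index with its own replicate (0.203) lay between those with the RSC libraries (0.202 and 0.213). The same holds for its sequencing run, separate by the list names, and for a difference of stage, since the list name of replicate 1 carries 8C.

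Of the 1228 regions gained at 20 h, 407 (33.1%) were listed in neither 72 h Omni-ATAC library, and 302 (24.6%) in no 72 h list of either protocol. Omni-ATAC missing such regions is excluded as the whole cause, since 25.8% of the 407 had a peak in the pooled 72 h ATAC list. After a shift of 50 kb that list met 26.9% of the regions present in both 20 h libraries, so the 25.8% does not exceed such overlap. Turnover of low-ranked peaks cannot be told apart: the share was 5.65 times that of regions of the same rank (5.87%), but regions gained at 20 h were chosen for absence at 12 h, the ratio ran from 2.13 to 9.21 over the steps, and crossed pairs of 12 h and 20 h libraries, chosen for absence in the same way, gave shares of 37.8% to 50.6%. Chance peaks shared by the 20 h libraries, which both steps use, cannot be told apart for a part of them, since crossed pairs gave 40 to 105 such regions. A change between 20 h and 72 h embryos stays open and untested.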
